A study of Mus musculus with 2 samples.

How the data were processed

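Chromatin carrying H3K4me2 (histone H3 dimethylated at lysine 4) was measured by ChIP-seq in mouse liver at postnatal day 0. The tissue came from mice of strain B6NTac;B6NCrl/Lap, pooled over both sexes. There was 1 group with 2 biological replicates. Replicate 1 was a pool of 15 mice with 1 technical replicate. For replicate 2 the labels give no number of mice and name technical replicates 1 and 2. The library size range was 300 to 500 bp in both.

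The values were 4 peak lists in narrowPeak format on mm10, each called against a control that was not analysed here. The lists were those of replicate 1, of replicate 2, of both replicates' reads pooled, and of the pooled peaks that the authors call replicated. The deposited signal value of each peak is its enrichment over the control as the authors computed it, with no formula given in the sources used here. The deposited significance values are -log10 p and -log10 q per peak, as the authors computed them. The peak caller, aligner and thresholds are not given in the sources used here. The lists hold no read counts, so the depth of each sample is unknown, and no interval that needs a depth was computed. Enrichment was compared only within a list, or by rank and correlation between lists. Signal tracks and alignments were not used here.

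Peaks on the 19 autosomes, X and Y were merged into regions and set against the GRCm38.p6 genome, the same assembly, and the GENCODE vM21 basic annotation. TSSs were those of protein-coding transcripts of 21826 protein-coding genes. A promoter was marked when a region lay within 1 kb of any TSS of the gene. Promoter breadth was the number of bases covered by regions within 5 kb each side of the gene's most covered TSS. Regions over 2 kb from every protein-coding TSS counted as away from promoters, and their number within 50 kb of that TSS was taken per gene. Promoters were CpG-rich when the 500 bases each side of the 5'-most TSS had an observed/expected CpG ratio of at least 0.6 and a GC fraction of at least 0.5. Coordinates are 1-based.

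A region of a replicate was found in the other when a region there covered at least 50% of its length. Overlap with the other replicate and with promoters was tested one-sided against 100 circular shifts of the regions along each chromosome, so that the smallest permutation p is 0.0099. The 26 gene lists, the test of each result and the rule for named genes were fixed before the data were examined. Marked shares of lists were tested with Fisher's exact test, two-sided, against all other protein-coding genes. Breadth and regions away from promoters were tested two-sided against 10000 random lists of the same size, so that the smallest permutation p is 0.0002. The difference between the erythroid and hepatocyte lists used 100000 reassignments of genes. Benjamini-Hochberg adjustment was made over the 26 lists, at a threshold of 0.05. Genes are the units in these tests and are not independent replicates of the experiment. Members that share regions count as separate genes in all list tests, so p can be too small. An example, chosen after its values were seen, is Hadha and Hadhb with 5665 covered bases each.

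Presence of 11 consensus motifs and 4 reversed control strings was compared between the central 1 kb of regions away from promoters and a paired window 5 kb to a side that held no region. The exact binomial (McNemar) test on discordant pairs was two-sided, with Benjamini-Hochberg adjustment over the 15 strings. Ratios of discordant pairs carry exact Clopper-Pearson 95% intervals.

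The 30 fixed genes are all named in the text. Further names were taken from the 10 genes with the widest region over the TSS and the 5 with the highest promoter enrichment. Names also came from the 2 most and 2 least covered members of each list, and from 5 marked in either replicate alone. Not every most or least covered member is named. Others are said to have been chosen after their values were seen. Alternatives covered the peak list, a minimum -log10 q of 2, each replicate alone, the overlap rule, window sizes, matched random lists and the motif background. In a list described as without a replicate, the other replicate's list took the place of the replicated list.

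The tests were tested on simulated data. A planted overlap of 60.0% was recovered as 60.0%. The breadth test called 96 of 100 planted lists and 3 of 100 null lists, and the marked-promoter test called 96 and 0. The planted gain in covered bases was far larger than the excess of the lists that did not pass the breadth test below. For marked promoters only a strongly lowered share was planted. These counts therefore do not give the power for smaller differences or for a raised marked share. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0, matplotlib 3.10.9 and samtools 1.23.1. Peaks on contigs and lncRNA genes were left out of the tests, because the annotation tests were set up for protein-coding genes on chromosomes. The symbols Ahsp and Amy2b were not found in the annotation, and H19 and Meg3 are lncRNA genes.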

Results

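H3K4me2 was mapped in newborn mouse liver, a tissue that at this age holds hepatocytes together with blood-forming cells. The design has 1 group of 2 biological replicates and no second condition, so comparisons were made between the replicates and between gene groups or regions. The replicate 1 list held 66376 peaks over 54.6 Mb and the replicate 2 list 58024 peaks over 56.6 Mb. The pooled list held 65475 peaks over 66.6 Mb. The replicated list held 45115 peaks over 61.1 Mb, which is 2.24% of the genome, and gave the main values below. Its median peak width was 883 bases and its median enrichment 6.79. Read depth is unknown. Values over both replicates are means ± SD of the 2 replicate lists (n = 2).

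The mark was found at most promoters and was broadest and strongest there. Of 21826 protein-coding genes, 14834 (68.0%) had a marked promoter. In the replicate lists 14662 genes were marked in both, 227 in replicate 1 only and 225 in replicate 2 only. Regions within 1 kb of a TSS made up 36.0% of regions (16254 of 45104), against a mean of 3.49% and a maximum of 4.04% for shifted regions (permutation p = 0.0099, one-sided, the smallest that 100 shifts give). They had a median width of 2069 bases and a median enrichment of 24.1, and held 61.5% of all covered bases. The 26948 regions over 2 kb from every TSS had a median width of 624 bases and a median enrichment of 4.92. Introns held 34.5% of regions and intergenic sequence 25.7%, against 35.8% and 58.4% for shifted regions. CpG-rich promoters were marked in 9822 of 10033 genes (97.9%) and CpG-poor promoters in 5012 of 11793 (42.5%), an odds ratio of 63.0 with Fisher's exact test.

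Hepatocyte genes carried broad marks. In the hepatocyte list, 33 of 36 promoters were marked (Fisher's exact adjusted p = 0.0027). Members had a mean of 4536 covered bases within 5 kb of the TSS, against 2157 in random lists of the same size (permutation adjusted p = 4.33e-04). Before adjustment this p was 0.0002, the smallest the permutations give. The replicate lists gave 4104 ± 215. Prox1 and Cebpa, transcription factors of the hepatocyte lineage, were the most covered members. Prox1 had 8821 ± 18.4 covered bases, with a region of 8951 bases on chromosome 1 (190166994 to 190175944). Cebpa had 6841 ± 44.5, with a region of 6939 bases on chromosome 7 (35116755 to 35123693). Hnf4a, another hepatocyte transcription factor, had 5108 ± 478, Ttr, a plasma carrier protein, 4799 ± 290, and Apoa1, the main protein of high-density lipoprotein, 3516 ± 719. Alb, which encodes serum albumin, had 2081 ± 380. Its peak enrichment was 4.60 in the replicated list, 7.85 in replicate 1 and 3.23 in replicate 2. Enrichment is not on a known common scale between lists, so these values do not show a difference between the replicates. Tdo2, a tryptophan-degrading enzyme, had 0 covered bases in the replicated list and in both replicates, and Serpina6 had 0 in the replicated list. Marked promoters of this list often had no TSS inside a region: 11 of 33, against 6.03% in random lists of marked genes (permutation adjusted p = 0.0017) and 18.5% in lists matched on CpG content (permutation p = 0.048, adjusted 0.312).

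Metabolic gene groups of the liver were also broadly marked against random lists of the same size. Housekeeping genes (mean 4537 covered bases) and cell cycle genes (4767) were too, so this breadth was not specific to liver lists. The list of bile acid synthesis and adult P450 genes did not pass against random lists of the same size. Mean covered bases were 4851 for gluconeogenesis and glycogen genes, 4352 for fatty acid oxidation, 4036 for cholesterol and lipid synthesis (permutation adjusted p = 4.33e-04 for each) and 4364 for the urea cycle (permutation adjusted p = 0.002, and 0.0751 within 2 kb). All 17, 20 and 20 promoters of the first 3 lists were marked, as were 9 of 10 urea cycle promoters, which did not pass (Fisher's exact adjusted p = 0.252). Foxo1 had 6250 ± 345 covered bases, Ppara, the fatty acid-sensing receptor, 6448 ± 489, Hmgcr, the rate-limiting enzyme of cholesterol synthesis, 5395 ± 589, and Ass1 of the urea cycle 5430 ± 53.0. Pck1, the entry enzyme of gluconeogenesis, had 3473 ± 233. The least covered members of these lists were lower: Gck had 2790.5 ± 646, Fgf21 483.5 ± 684, Mvk 1715 ± 195 and Otc 1758 ± 824. Cps1, the first enzyme of the urea cycle, had a region within 1 kb of a TSS in replicate 1 only (enrichment 3.82) and none there in the replicated list, with 2586 ± 31.8 covered bases within 5 kb. Genes of bile acid synthesis and adult P450 enzymes had a mean of 1863 covered bases, and 17 of 26 promoters were marked; neither passed the test (adjusted p = 0.534 by permutation and 0.867 by Fisher's exact test). Against CpG-matched lists they lay 1138 bases higher (permutation adjusted p = 0.0016). Its members ranged from Slc10a1, the bile acid uptake carrier, with 5660 ± 465, to Cyp1a2 and Cyp2a5 with 0. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 3417 ± 639, and Cyp2e1 had 1587 ± 993. Coagulation and complement genes had a mean of 3009 covered bases (permutation adjusted p = 0.0468). That call was lost with either replicate alone (permutation adjusted p = 0.0688 without replicate 1 and 0.187 without replicate 2), with the stricter threshold and for peaks found in both replicates (0.0532 each by permutation), and within 2 kb (0.158 by permutation). It was also lost among marked genes alone, where members lay 301 bases above random lists (permutation adjusted p = 0.5145). Against CpG-matched lists the excess was 2103 bases (permutation adjusted p = 5.78e-04).

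Fetal liver genes were marked at 16 of 16 promoters, with a mean of 4737 covered bases (permutation adjusted p = 4.33e-04). Igf2bp3, which encodes a fetal RNA-binding protein, had 8942 ± 364 covered bases and a region on chromosome 6 (49212116 to 49219572). Igf2, the fetal growth factor, had 8065 ± 269, and its lncRNA neighbour H19, outside the tests, had 4192 ± 279. Afp, encoding alpha-fetoprotein, had 2639 ± 235, with its TSS outside the region. Bex1 with 599 ± 77.8 and Plagl1 with 1619.5 ± 227 were the least covered members.

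Erythroid genes had the most covered bases of the 26 lists. Their mean was 5963 covered bases in the replicated list and 5584 ± 293 over the replicate lists (permutation adjusted p = 4.33e-04), and 26 of 27 promoters were marked (Fisher's exact adjusted p = 0.0017). Nfe2, an erythroid transcription factor, had 9669 ± 38.2 covered bases and a replicated region of 9785 bases on chromosome 15 (103250055 to 103259839). Bcl11a, a repressor of fetal globin genes, had 9461 ± 89.8 and a replicated region of 10524 bases on chromosome 11 (24073587 to 24084110). Tal1, a master regulator of blood formation, had 8677 ± 129 over the replicate lists and a replicated region of 8628 bases on chromosome 4 (115055742 to 115064369). Gata1 had 6321 ± 779, Klf1 4560 ± 273 and Epor, the erythropoietin receptor, 4261 ± 228. The 2 least covered members in the replicated list were Slc25a37, a mitochondrial iron carrier, with 0 there and in both replicates, and Hbb-bs, a beta-globin gene, with 1015. Over the replicate lists Hbb-bs had 1782 ± 104. The globin genes include near-identical copies, so reads there are hard to place and their values are uncertain.

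The erythroid list was more broadly covered than the hepatocyte list. The means were 5963 ± 2160 bases (SD over 27 genes) and 4536 ± 2006 (36 genes), a difference of 1428 bases (permutation p = 0.0074, two-sided). Within 2 kb of the TSS the difference was 616 bases (permutation p = 0.0196). The list with the higher share of genes under a peak changed with position, and no test was made at single positions. At 700 bases upstream of the 5'-most TSS a peak covered 75.9% ± 7.86 of erythroid and 27.8% of hepatocyte genes. At 1 kb downstream the shares were 66.7% and 84.7% ± 5.89, and at 2.3 kb downstream 75.9% ± 2.62 and 81.9% ± 1.96. At 3 kb downstream a peak covered 83.3% ± 2.62 of erythroid, 63.9% of hepatocyte, 29.2% ± 5.89 of housekeeping and 11.4% ± 0.554 of all protein-coding genes. At the TSS itself the shares were 70.4%, 50%, 79.2% ± 5.89 and 57.4% ± 1.03.

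**Figure D1:**
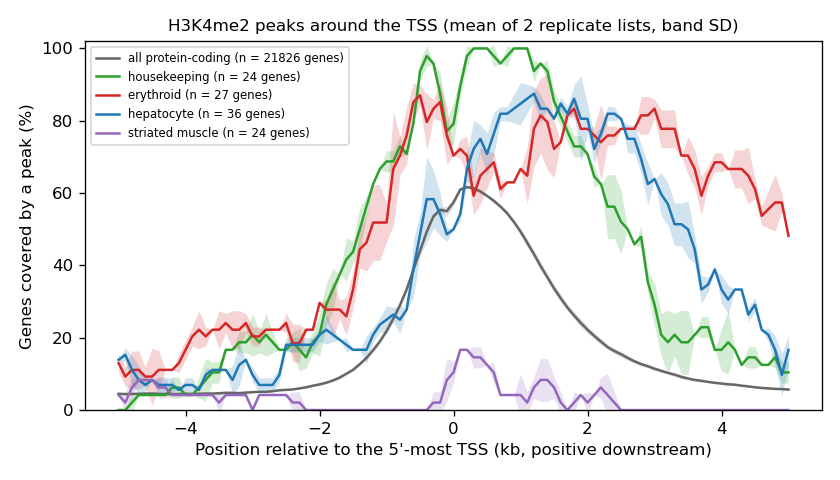
Percent of genes with a peak at each position within 5 kb of the 5'-most TSS (kb, positive downstream), as the mean of the 2 replicate lists with the SD as a band. The erythroid and hepatocyte lines stand at 75.9% and 27.8% at 700 bases upstream, at 66.7% and 84.7% at 1 kb downstream and at 83.3% and 63.9% at 3 kb downstream, where the line of all protein-coding genes stands at 11.4%.

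Other blood lists were less uniform. Stem and progenitor genes had a mean of 3755 covered bases (permutation adjusted p = 0.0041, and 0.0881 within 2 kb) and 16 of 18 marked promoters, which did not pass (Fisher's exact adjusted p = 0.121). They were led by Meis1 with 7897 ± 38.9 and Runx1, required for blood stem cells, with 7804 ± 324. Slamf1 had 0. Lists of granulocytes and mast cells (2397 covered bases), macrophages (1879), B-lineage cells (2521) and megakaryocytes (1663) did not pass the breadth test (permutation adjusted p from 0.434 to 0.610). Each held broadly marked members and members at 0: Fli1 with 7177 ± 580 against Mpl with 0 in the megakaryocyte list, Prtn3 with 6060 ± 657 against Cpa3 with 0 in the granulocyte and mast cell list, Id3 with 7059 ± 233 against Cd163 with 0 in the macrophage list, and Pax5 with 5749 ± 56.6 against Dntt with 0 in the B-lineage list. Among fixed genes, Itga2b of the megakaryocyte list had 2507 ± 864, Elane of the granulocyte list 2616 ± 246 and Adgre1 of the macrophage list 781 ± 462. Against random lists matched on CpG content, granulocyte, macrophage and B-lineage genes lay higher (permutation adjusted p = 0.0012, 0.0292 and 0.0022). The T and NK cell list was lower, with a mean of 1052 (permutation adjusted p = 0.0309) and 4 of 16 marked promoters (Fisher's exact adjusted p = 0.0016). That breadth call was lost with CpG matching (permutation adjusted p = 0.406) and among marked genes alone, where the 4 members lay 830 bases above random lists (permutation adjusted p = 0.468). Gata3 had 7479 ± 629, while Cd3e and Cd3g had 0. The replicates differed in these groups: replicate 2 had 592 more covered bases than replicate 1 in the granulocyte and mast cell list, 333 more in the macrophage list and 615 more in the B-lineage list, against 68.2 more over all genes.

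Non-parenchymal liver cell lists did not pass the breadth test. Mean covered bases were 2699 for endothelial, 2506 for stellate and mesenchymal and 2761 for bile duct genes (permutation adjusted p = 0.274, 0.489 and 0.326). Endothelial genes had 655 more covered bases in replicate 2 than in replicate 1. They passed the breadth test against CpG-matched lists (permutation adjusted p = 0.0166). Gata4 had 7595 ± 305, Egfl7 4408 ± 1468 and Stab2, a scavenger receptor of sinusoidal endothelium, 732 ± 563. Reln had 5266 ± 1030 and Lrat, which stores retinol in stellate cells, 1694 ± 203, while Lum had 0. Sox9, a bile duct transcription factor, had 4014 ± 95.5 and Krt19 298 ± 3.54.

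Cell cycle genes (mean 4767) and housekeeping genes (4537) were broad, with all 20 and 24 promoters marked (permutation adjusted p = 4.33e-04 for breadth of each). Rrm2, a subunit of ribonucleotide reductase, had 7617 ± 365, Actb 7118 ± 457 and Gapdh 5282 ± 91.2. Markers of other organs were narrow: neurons 1046 (permutation adjusted p = 0.0052), pancreas and intestine 677, epidermis 598, germline 474 and striated muscle 341 (permutation adjusted p = 4.33e-04 for each). Marked promoters numbered 17 of 24 in the neuron list, which did not pass the test (Fisher's exact adjusted p = 0.867). They numbered 6 of 23, 5 of 20, 3 of 22 and 5 of 24 in the other 4 lists, all lower (Fisher's exact adjusted p from 5.38e-06 to 6.49e-04). Among marked genes alone, the breadth calls for pancreas and intestine, epidermis and germline did not pass (permutation adjusted p = 0.432, 0.118 and 0.0752), with 6, 5 and 3 members left. The differences from random lists were then -752, -1271 and -1684 bases, against -1476, -1551 and -1685 over all genes. These differences have different baselines. For germline the list mean rose from 474 to 1427 bases among marked genes, and the mean of random lists from 2159 to 3111. The call of epidermis was also lost with CpG matching (difference -489 bases, permutation adjusted p = 0.156). Neurod1 had 852 ± 375 and Pdx1 646 ± 58.0, while Myod1, the muscle determination factor, had 0. Developmental transcription factors had a mean of 2140, near random lists (permutation adjusted p = 0.960), and lay lower against CpG-matched lists (permutation adjusted p = 0.0015). They ranged from Gata6 with 9246 ± 445 to Hoxb1 with 0, and Hoxa13 had 1248 ± 216.

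**Figure D2:**
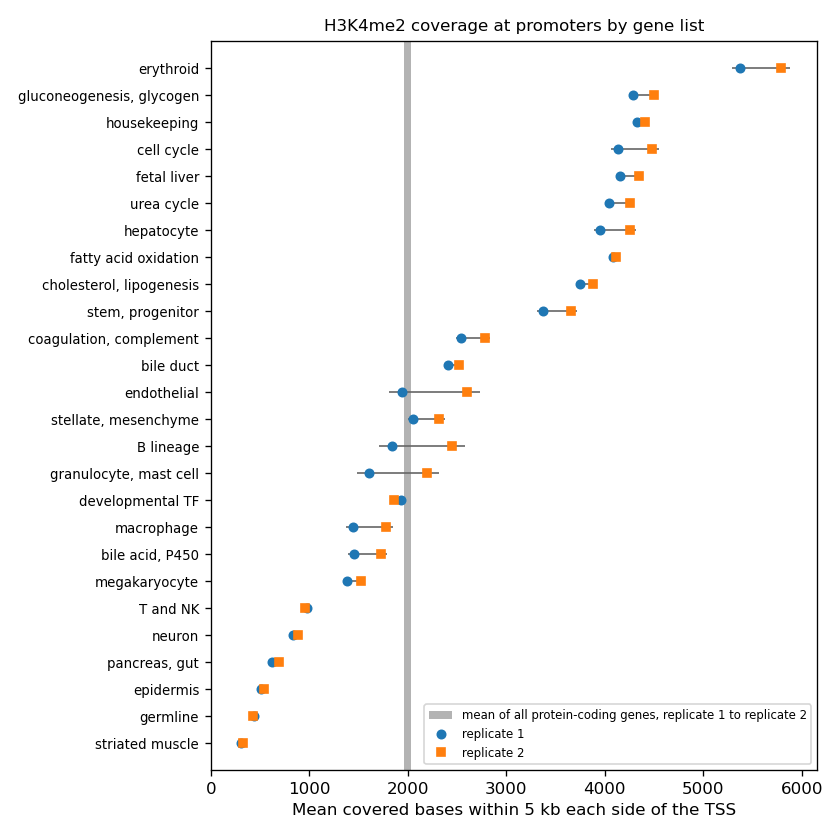
Mean covered bases within 5 kb each side of the TSS for the 26 gene lists, with a circle for replicate 1, a square for replicate 2, a bar for the SD around their mean (n = 2) and a grey band between the means of all protein-coding genes. The erythroid list stands highest at 5377 and 5792 bases, and striated muscle lowest at 306 and 322.

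Regions away from promoters were most numerous around erythroid genes. Within 50 kb of the TSS, erythroid members had a mean of 5.67 such regions, against 1.95 in random lists (permutation adjusted p = 0.0026). Gluconeogenesis genes had 4.18, hepatocyte genes 4.03, housekeeping genes 3.88, granulocyte and mast cell genes 3.85, endothelial genes 3.82 and megakaryocyte genes 3.73 (permutation adjusted p from 0.0026 to 0.0442). Neuron genes had 0.625 (permutation adjusted p = 0.0065), and the other 18 lists, from 0.85 in epidermis to 3.35 in fatty acid oxidation, did not pass. Counts were higher in the replicate lists, and the order after the erythroid list changed. They were 9.30 in replicate 1 and 8 in replicate 2 for erythroid, 7.5 and 6.31 for hepatocyte, 6.73 and 5.53 for megakaryocyte, 6 and 6 for endothelial, 5.8 and 5.85 for granulocyte and mast cell, 6.75 and 4.88 for housekeeping and 5.82 and 5.29 for gluconeogenesis genes. Each of these 7 lists and the neuron list passed with either replicate left out. The calls for megakaryocyte and granulocyte genes were lost within 100 kb (permutation adjusted p = 0.0676 and 0.089) and for peaks found in both replicates (0.0639 and 0.0947 by permutation).

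Binding motifs of liver and blood transcription factors were more common in regions away from promoters than in flanking windows. Of 25936 pairs, 26.8% of regions and 20.7% of flanks held the GATA motif, a ratio of pairs with it only in the region to pairs with it only in the flank of 1.40 (95% interval 1.34 to 1.46; exact adjusted p = 1.32e-57). The ratio was 4.21 for CTCF (3.59 to 4.97), 4.04 for HNF1 (2.56 to 6.61), 2.41 for NF1 (1.34 to 4.53) and 1.65 for PU.1, a myeloid and B-cell factor (1.54 to 1.76). It was 1.38 for C/EBP, 1.31 for FOXA, 1.25 for MEF2, 1.10 for HNF4A and 1.07 for AP-1, all past the threshold. The RFX motif did not pass (ratio 1.91, exact adjusted p = 0.127). The reversed strings of HNF4A and PU.1 gave 1.03 each and did not pass, and those of FOXA and GATA were less common in regions, at 0.870 and 0.808. The interval of HNF4A (1.06 to 1.15) overlapped that of its reversed string (0.978 to 1.08). The ratios were not tested against each other, so this overlap does not decide whether they differ. The intervals also overlapped at the stricter threshold and for peaks found in both replicates. They lay apart in the pooled list (1.10 to 1.17 and 0.994 to 1.07) and for the central 500 bases (1.10 to 1.22 and 0.955 to 1.09). They were also apart, more narrowly, with either replicate alone. Against a background matched on GC content the ratio was 7.23 for HNF1 (4.03 to 14.1) and 3.596 for CTCF (3.07 to 4.23). For HNF4A it was 1.06 (1.02 to 1.11), beside 1.03 (0.974 to 1.08) for its reversed string. There the reversed FOXA string did not pass (ratio 0.974, exact adjusted p = 0.318), while those of GATA and PU.1 were less common in regions, at 0.872 and 0.854. Mean GC content was 48.1% in regions and 45.0% in flanks.

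**Figure D3:**
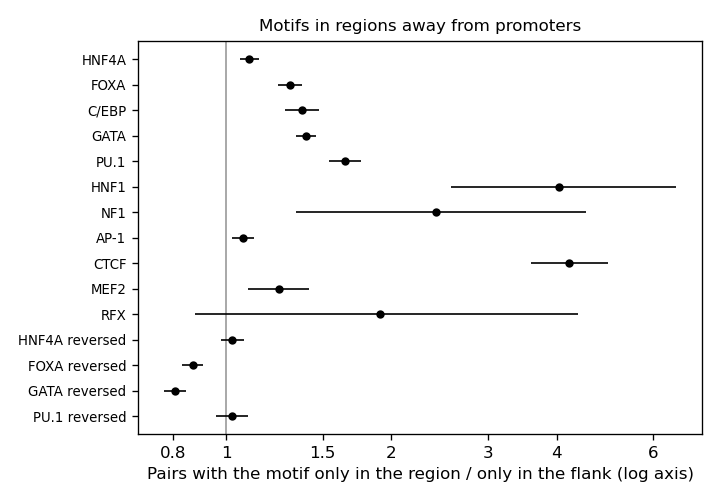
Number of pairs with the motif only in the region divided by the number with it only in the flank (log axis), with 95% exact intervals, for 11 motifs and 4 reversed control strings over 25936 pairs. CTCF at 4.21 and HNF1 at 4.04 are highest (3.596 and 7.23 against a GC-matched background, not drawn), and the reversed strings lie between 0.808 and 1.03.

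The widest replicated region covered the TSS of Epb41, which encodes a protein of the red cell membrane skeleton, and that of Gm10300 and spanned 14562 bases on chromosome 4 (132065297 to 132079858). A region of 13737 bases on chromosome 8 (84967688 to 84981424) covered the TSSs of Junb, Prdx2, Rnaseh2a and Gm49661. Next were Sdc4 (13320 bases, chromosome 2, 164431117 to 164444436), Kdm6b, an H3K27 demethylase (12959 bases, chromosome 11, 69407898 to 69420856), Ank1, the red cell ankyrin (12574 bases, chromosome 8, 23032837 to 23045410), and Setd1b, an H3K4 methyltransferase (12133 bases, chromosome 5, 123134329 to 123146461). The region over Ank1 lay wholly inside the annotated gene, with 1.17% of its bases in coding-transcript exons. The highest promoter enrichment was 77.1 at Rusc1, followed by Dusp7 (70.5), Fam78a (70.0) and the shared promoter of Akr7a5 and Pqlc2 (69.0).

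The replicates shared most of their covered bases and nearly all strong peaks. Shared bases came to 46.8 Mb, which is 85.8% of replicate 1 and 82.8% of replicate 2. Of regions, 68.0% of replicate 1 and 65.4% of replicate 2 were found in the other, against means of 2.09% and 1.91% for shifted regions (permutation p = 0.0099 for each, one-sided, the smallest that 100 shifts give). Of the 10% of peaks with the lowest enrichment, 32.5% and 31.1% were found in the other replicate, and of the 10% with the highest, 99.7% and 98.5%. Peaks within 1 kb of a TSS were found in 91.2% and 88.5% of cases and others in 58.5% and 55.1%. Over the 40049 of 45104 replicated regions that had a peak in both replicates, enrichment had a Spearman rho of 0.907 and a Pearson r of 0.939 on the log2 scale. Regions that lacked a peak in a replicate were left out, so the correlation covers only regions called in both. This correlation is across regions, which are not independent replicates. Away from promoters rho was 0.750. The strongest promoters marked in replicate 1 only were Art1, Epha8, Npffr1, Heph and Hsf3, and in replicate 2 only Mia, Chrm1, Lefty1, B430306N03Rik and Tslp. Within 5 kb of the TSS, Art1 (1203 ± 23.3), Mia (2304 ± 755), Chrm1 (1308 ± 220), Lefty1 (1586 ± 53.0), B430306N03Rik (2488 ± 361) and Tslp (1369 ± 284) had covered bases in both replicates.

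**Figure D4:**
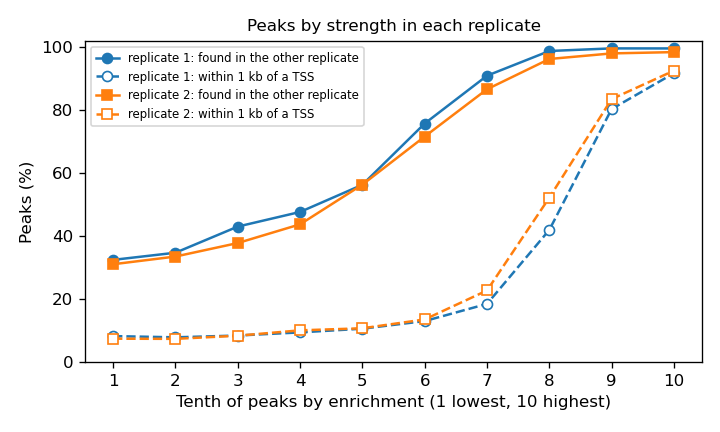
Percent of peaks found in the other replicate (solid lines) and percent within 1 kb of a TSS (dashed lines), in 10 equal groups of each replicate's peaks ordered by enrichment, from 1 (lowest) to 10 (highest). The share found rises from 32.5% and 31.1% to 99.7% and 98.5%.

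The X chromosome carried fewer regions than the autosomes. It had 5.93 regions per Mb, while autosomes ranged from 12.7 on chromosome 14 to 28.1 on chromosome 11. Promoters were marked for 51.7% of X-linked and 69.3% of autosomal protein-coding genes. Single autosomes ranged from 54.2% on chromosome 14 to 81.9% on chromosome 12, so the share on X lay close to the lowest autosome. These values were not adjusted for the number of X and Y copies in the pooled sexes, and no test was made. On Y, 4 of 183 genes were marked.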

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

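The tests of the peaks that lack a replicate's peak were chosen after the result was seen, and the gene lists compared between the replicates were picked after their coverage was seen, although all 26 lists were tested. The test matched on covered bases and enrichment of the window was added once the one matched on promoter enrichment had been seen.

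Signal appeared in data that the comparisons left out. The replicated list held 11 peaks on unplaced or unlocalised contigs, with enrichment up to 14.4. Among 6983 lncRNA genes over 10 kb from every protein-coding TSS, 1009 had a replicated region within 1 kb of a TSS.

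Replicate 2 had more covered bases than replicate 1 at promoters of 4 lists: endothelial (655 more; Egfl7 3370 and 5446), B-lineage (615; Cd79b 2748 and 4180), granulocyte and mast cell (592; Ngp 652 and 2951) and macrophage (333; C1qc 228 and 1268), with genes chosen after their values were seen, and the erythroid (415), cell cycle (347), hepatocyte (303), stem and progenitor (287) and bile acid and P450 lists (278.5) also passed when matched on promoter enrichment (permutation adjusted p from 0.0013 to 0.0484) but not with window matching (permutation adjusted p from 0.0555 to 0.430). If weaker promoter enrichment, or weaker or broader regions around these promoters, were the cause, matched lists would show the same excess, but the first 4 lists stayed above lists matched on either (permutation adjusted p from 0.0017 to 0.0156 when matched on covered bases and enrichment of the window). A smaller share of hepatocytes in the tissue pool of replicate 2 was predicted to put the hepatocyte list below matched lists. The list lay 196.7 bases above lists matched on enrichment (permutation p = 0.0032), and 99.3 above with window matching (permutation p = 0.198). Covered bases count called peaks and need not fall when the share falls modestly, so these values do not decide on this cause. A larger share of myeloid, B-lineage and endothelial cells in replicate 2 is a hypothesis not tested here, and since each replicate is a single pool, a library difference stays open too. The T and NK, bile duct and megakaryocyte lists did not pass with either matching, developmental transcription factors had 70.8 fewer bases in replicate 2 and passed with both (permutation adjusted p = 0.0031 and 0.0039), and Gata4, Tek and Erg of the endothelial list also stand in another list.

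In the replicated list 5156 peaks lacked an overlapping peak in 1 or both replicate lists at 50% of either peak's length. They may be weak peaks near the limit of the calls: 45.3% of the lowest 10% of peaks by enrichment lacked one, against 0.0133% (3 peaks) of the upper 50%. Peaks shifted so far that they only touch would meet both replicates, and only 1.96% touched a peak of each by at least 1 base. For split peaks this value decides nothing. A split peak inside a replicated peak overlaps by its whole length and passes the rule, so it could not be among these peaks. How the authors admitted these peaks is not given in the sources used here. No biological explanation was tested.

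Erythroid promoters were more broadly covered than hepatocyte promoters by 1428 bases. Within classes of CpG content the difference was 1369 bases (permutation p = 0.0092), among genes with no other TSS within 10 kb it was 1642 (permutation p = 0.0123; 18 and 26 genes), and with each gene's 5'-most TSS it was 1195 (permutation p = 0.0233). None of these 3 explanations alone removes the difference. A larger share or another state of erythroid cells may account for it, and no such biological explanation was tested, since cell numbers in the tissue are unknown.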

How the results depend on the processing

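The alternatives that keep only peaks found in both replicates or only genes with a marked promoter were chosen after seeing the data. Of 104 summary values under alternatives, 93 kept their side of the threshold or stayed within their spread, 11 moved and 0 reversed. The erythroid excess over the hepatocyte list ranged from 616 (2 kb window) to 1536 bases over its alternative settings, with permutation p from 0.0038 to 0.0196. It was 1642 (permutation p = 0.0123) among genes with no other TSS within 10 kb and 1195 (permutation p = 0.0233) with the 5'-most TSS. Covered length was 61.1 Mb, and 66.6 Mb in the pooled list and 54.6 to 56.6 Mb without either replicate. The replicated share of the pooled list was 68.9%, and 75.1% at -log10 q of at least 2, where fewer weak peaks enter. The correlation was 0.907, 0.916 with -log10 p and 0.750 away from promoters. Lists with narrower coverage numbered 6, and 2 among marked genes. Lists with fewer regions away from promoters numbered 1, and 2 in the pooled list, without replicate 1, without replicate 2 and with gene-density matching. The cause of these moves was not tested except as stated.

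Against CpG-matched lists, the bile acid and P450 list (1138 bases above, permutation adjusted p = 0.0016) and the macrophage list (845 above, permutation adjusted p = 0.0292) reversed from below random lists, and lists with broader coverage numbered 16 in place of 11. Among marked genes the T and NK list reversed to 830 above (permutation adjusted p = 0.468, 4 members). The reversed PU.1 string fell to a ratio of 0.854 against the GC-matched background. The cause was not tested. Of list values per alternative, 152 of 156 for marked promoters, 188 of 208 for breadth and 195 of 208 for regions away from promoters kept their call or lack of one, as did 103 of 105 motif values. Depth limits what is called weak or absent, since a promoter without a peak may still carry the mark.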

Other observations

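Of 10137 lncRNA genes, 3031 (29.9%) had a replicated region within 1 kb of a TSS, counted at any distance from protein-coding TSSs. H19, an imprinted lncRNA gene expressed in fetal liver, had a region of 3214 bases on chromosome 7 (142575569 to 142578782).

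Marked promoters of hepatocyte genes often had no TSS inside a region, in 33.3% of cases (11 of 33), against 6.03% in random lists of marked genes (permutation adjusted p = 0.0017); the 11 include Alb, Apob, Hnf4a and Ttr, chosen after their values were seen. Low CpG content of these promoters may explain part of it: lists matched on CpG content gave 18.5%. The excess over these passed the threshold set for this test only narrowly (permutation p = 0.048) and did not pass when adjusted over all 26 lists (permutation adjusted p = 0.312), so whether CpG content accounts for all of it is weakly decided. The pattern was also seen for macrophage (7 of 12), B-lineage (6 of 11), granulocyte (6 of 13), gluconeogenesis (5 of 17), bile acid and P450 (5 of 17) and stellate genes (5 of 19) against unmatched lists (permutation adjusted p from 0.0017 to 0.0357), and none of them passed with CpG matching when adjusted over all 26 lists (permutation adjusted p from 0.117 to 1). The excess stayed large for macrophage (58.3% against 21.0%, permutation p = 0.0066 before adjustment) and B-lineage genes (54.5% against 21.4%, permutation p = 0.0244). The 7 macrophage genes include C1qa, C1qb and C1qc, chosen after their values were seen and counted as separate genes. Whether related members make these p-values too small was not tested. The other 4 had 46.2%, 29.4%, 29.4% and 26.3% against 24.5%, 13.7%, 26.8% and 11.1%. Developmental transcription factors had 12.8% (5 of 39) against 2.91% (permutation p = 0.009, adjusted 0.117) and did not pass against unmatched lists.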
